A study of Mus musculus with 3 samples.

How the data were processed

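Gene expression was measured on 3 Agilent mouse microarrays, each hybridised with Cy3-labelled RNA in 1 channel. Per the labels, the RNA came from primary mesenchymal stem cells (MSCs) of mouse bone marrow, taken before induction (day 0) or after 3 or 21 days in medium with ascorbic acid and beta-glycerophosphate. Ascorbic acid is needed for collagen maturation, and beta-glycerophosphate is a phosphate source for mineral. The labels gave 3 groups with 1 array each, so no comparison had replicates, no test between groups was possible, and no p-value was computed. All 3 comparisons between days were made. The day 0 and day 21 arrays shared a slide and a scan, and the day 3 array was alone on the second slide and scan.

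The deposited scanner files hold linear spot intensity from Agilent Feature Extraction. Per the file headers the version was 10.10.1.1, whereas the submitters' processing notes name version 12.0; the values came from the files. Per the file headers, the processed signal was background-subtracted and detrended within each array, and it was not scaled between arrays. The deposited value table of the series held the same intensity as the scanner files, with a largest relative difference of 0, so its scale was linear, its values were not centred, and no direction was left open.

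Each array held 59305 non-control spots. Log2 of the processed signal was taken and the array's 75th percentile over the non-control spots was subtracted. That percentile was 172.2 at day 0, 174.6 at day 3 and 190.7 at day 21. Spots marked as non-uniform or as population outliers were left out, 200, 115 and 146 of them on the day 0, day 3 and day 21 arrays. The remaining spots of a probe were averaged on the log2 scale. Of 55681 non-control probes, 17 had no usable spot on at least 1 array and were left out. No non-control spot was saturated. Well above background means Feature Extraction's own mark for at least 50% of a probe's spots.

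Probes were named through their transcript accessions, without versions, in a RefSeq gene table of the assembly GRCm38.p6, from which no position was used. In that way 26755 probes matched 1 gene and 28909 stayed unnamed. The named probes covered 20279 genes, of which 14876 had 1 probe and 5403 had 2 or more. A gene was represented by its probe with the highest mean over the 3 arrays. Where 2 or more probes of a gene were well above background on both arrays, the median SD between their differences was 0.14 for day 3 against day 0, 0.16 for day 21 against day 0 and 0.17 for day 21 against day 3. Probes of 1 gene differed by at least 2-fold in opposite directions in 0, 1 and 0 genes of these comparisons.

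A gene counted as measured in a comparison when its probe was well above background on both arrays. For a gene above background on 1 array only, the brighter value was set against the higher of the dim probe's own value and the lowest value among probes well above background on the dim array. Such a bound is given as an at-least fold. Genes were called higher or lower by a fixed rule of size, at least 2-fold. The technical spread came from 399 probes spotted 10 times on each array: the SD was 0.14 for a log2 value and 0.19 for a log2 difference. Feature Extraction's error model gave a median SD of 0.20 for a difference between day 3 and day 0. Both cover the array only, not cultures or animals, and the number of arrays limits the precision. Negative log2 differences mean lower on the later day.

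Before the data were examined, 34 gene lists were written, for osteoblast stages, other cell types the culture could hold, matrix, signalling, stress and metabolism, together with the comparisons, the alternatives and the rule for named genes. A list's median difference is given over its measured members, with an exact binomial 95% interval of the median over genes where there were at least 6 members. It is also given as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. These describe the 3 arrays and are not tests of the conditions. A further 8 lists were written after the largest differences had been seen and before their own values were computed. Named genes are 12 markers given whatever their value, the 8 measured genes most raised and the 8 most lowered in each comparison, and the 4 largest bounds in each direction, without clone or model names. From each list, up to 4 members with the largest absolute difference are named, plus members whose point is that they were not above background. Bounds named for other members were chosen after their values were seen.

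The calls were tested on simulated data for day 3 against day 0, and the list statistics on the real differences of that comparison. Day 0 values of 12455 genes received the technical noise, and 200 genes were changed. Of the genes changed 3-fold, 99.9% were called at the 2-fold rule, of those changed 1.5-fold 1.96%, and unchanged genes gave a mean of 0 calls per simulated array. The simulated noise, with an SD of 0.19 for a log2 difference, leaves out slides, RNA and cultures. The 0 calls were therefore fixed in advance and give no rate of false calls between single arrays. Of 200 random lists of 13 genes, 5.5% fell outside the 2.5th to 97.5th percentile with no shift, and 100% did after a shift of 1 (log2). Both shares were nearly fixed in advance. The lists came from the same genes as the random lists they were ranked against, and a shift of 1 is large beside the spread of such lists. They hold no genes chosen for a shared function, so they do not test the percentiles of the written lists.

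Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the 75th percentile of spots detected on all arrays, no scaling, scaling on 7 of the 10 Agilent spike-in probes, the deposited value table, and other filters, probe rules and thresholds. Normexp (limma 3.58.1, R 4.3.3) used the median spot signal, because a mean spot signal is not among the columns. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.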

Results

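The series followed mouse bone marrow MSCs, stromal cells that can form bone, cartilage and fat, through osteogenic induction. There were 3 groups, MSCs at day 0 and osteogenic cultures at day 3 and day 21, with 1 array each. There were therefore no replicates, no difference had a replicate check, and every comparison below is between single arrays. Of 20279 genes with a named probe, 12948 (63.8%) were well above background at day 0, 13126 (64.7%) at day 3 and 13441 (66.3%) at day 21. Across measured genes, Pearson's r between arrays was 0.95 for day 3 and day 0, 0.89 for day 21 and day 0, and 0.95 for day 21 and day 3 (genes are not independent replicates). The technical SD of a log2 difference was 0.19, and differences are log2 values unless given as folds.

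Day 3 against day 0 asked what differed after the first days of induction. Most measured late osteoblast and mineralisation genes were higher at day 3, most interferon response genes were many-fold higher, and many cell cycle and contractile genes were lower. Of 12455 measured genes, 963 were at least 2-fold higher and 978 at least 2-fold lower, and 335 and 164 passed 4-fold. Another 303 genes were at least 2-fold higher and 183 at least 2-fold lower by a bound. The genes most raised were Sult1a1, a sulfotransferase (149-fold), Lcn2, an iron-carrier binding protein (118-fold), Apod, a lipocalin (74.5-fold), the guanine deaminase Gda (68.9-fold), the interferon-inducible genes Ifitm1 (64.7-fold) and Ifi27l2a (56.7-fold), Clca3a2 (48.4-fold) and complement C4b (48.0-fold). Among the largest bounds were haptoglobin Hp (at least 1584-fold higher), the protease inhibitor Slpi (at least 693-fold) and the Wnt-binding protein Sfrp2 (at least 231-fold).

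The genes most lowered at day 3 were Lce1i (63.9-fold), the cationic amino acid transporter Slc7a3 (48.2-fold), the natriuretic peptide Nppb (33.5-fold), the receptor phosphatase Ptprz1 (28.6-fold), Cox6a2 (27.2-fold), Ifi27l2b (20.6-fold), Cyb5r2 (19.6-fold) and the stress pseudokinase Trib3 (19.4-fold). By a bound, Olfr781 was at least 96.7-fold lower, Lce1h at least 36.1-fold, Lce1g at least 24.7-fold and Lce1c at least 22.0-fold. The Lce1 genes are near-identical family members whose probes may take up each other's RNA, so their single values are uncertain. Ifi27l2a and Ifi27l2b, also closely related, differed in opposite directions.

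Of the osteoblast markers, Runx2, the lineage's transcription factor, differed by 0.12 at day 3 at a dim signal of 20.7, and Col1a1, the main bone collagen, by 0.06. Sp7 and Sost were not well above background on any array, and Bglap had no named probe. Alkaline phosphatase Alpl was not above background at day 0 and was at least 2.48-fold higher at day 3, bone sialoprotein Ibsp was at least 7.56-fold higher, and osteopontin Spp1 was higher by 1.74. Of 11 measured early osteoblast genes, 0 were 2-fold higher and 2 were 2-fold lower (Msx2, -1.81; Dlx5, -1.10), with Fgfr2 at 0.84. Their median was 0.12 (95% interval -1.10 to 0.72), at the 85.9th percentile of matched random lists, and changed sign under spike-in scaling (-0.47). Of 10 measured late genes, 6 were 2-fold higher and 2 lower, with a median of 1.70 (-1.04 to 2.70) at the 100th percentile. Omd, a bone matrix proteoglycan (2.92), Mgp (2.70) and Bglap2 (2.36) led the higher members. Bglap2 and Bglap3 are near-identical copies of osteocalcin, so their values are uncertain. The phosphate transporter Slc20a1 (-2.57) led the lower members.

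Cell division genes were lower at day 3: 13 of 30 measured passed 2-fold, with 0 higher, and the median was -0.91 (-1.07 to -0.76) at the 0th percentile. Cenpe (-1.93), Bub1 (-1.46), Rrm2 (-1.41) and Aurka (-1.39) led the group, and Mki67 was at -1.27. Of 11 cell cycle inhibitor and senescence genes, 3 were 2-fold higher, led by Cdkn1c (3.42) and Sesn1 (2.65), and the median of 0.43 (99.6th percentile) changed sign under spike-in scaling. Of 11 interferon response genes, 10 were 2-fold higher and 0 lower, with a median of 2.96 (1.03 to 4.38) at the 100th percentile. Oasl2 (5.03), Oas1a (4.38), Isg15 (4.07) and Usp18 (3.57) were the highest.

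Contractile genes were lower in 10 of 13 cases, with 1 higher and a median of -1.39 (-2.24 to 0.05) at the 0th percentile. They included Actg2 (-2.36), Cnn1 (-2.24) and Myh11 (-2.24), and Tpm1, whose 5 probes ran from -2.58 to 0.51. BMP and TGF-beta pathway genes had 9 of 17 lower and 1 higher, with 1 more lower and 2 higher by a bound (median -1.17, 0th percentile), with Inhba at -2.71. Wnt pathway genes had 6 of 14 higher and 1 lower, with 2 more each way by a bound (median 0.74, 99.98th percentile), among them the inhibitors Sfrp1 (4.55) and Wif1 (1.72), and the transcription factor Lef1 was at -3.24. In the insulin-like growth factor system 4 of 9 were higher and 2 lower (median 0.97, 99.99th percentile), led by the binding proteins Igfbp3 (4.41) and Igfbp4 (2.43). ER stress genes had 4 of 14 lower and 0 higher (median -0.58, 0.07th percentile), the largest being Trib3 (-4.28), Chac1 (-3.20) and Asns (-2.32). Hypoxia and glycolysis genes had 3 of 16 lower and 2 higher (median -0.53, 0.29th percentile), with Vegfa at -2.63. ERK response genes had 4 of 12 lower and 1 higher (median -0.55, 0.96th percentile), with Dusp4 at -2.85, and Notch pathway genes 3 of 7 lower and 1 higher (median -0.84, 0.65th percentile).

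Matrix and stromal genes differed in both directions at day 3. Of 26 collagen and collagen processing genes 6 were higher, among them Col6a2 (3.41) and Col14a1 (4.76 and 1.64 on its 2 probes), and 4 lower, led by the lysyl hydroxylase Plod2 (-2.56), at the 70.8th percentile. Of 20 non-collagenous matrix genes 6 were higher (Lum, 2.91; Ogn, 2.22) and 4 lower (Tnc, -2.56; Ccn2, -2.14), at the 91.2nd percentile. Proteases and inhibitors had 2 of 13 higher and 1 lower, with 3 more higher and 0 lower by a bound. Their median was 0.13 over measured members (90.7th percentile) and 0.62 with the 3 at their bound. Marrow stromal genes had 4 of 20 higher, led by Pdgfra (4.74), Angpt1 (3.74) and Ly6a (3.65), and 5 lower, led by Nes (-2.91); their median of 0.30 (99.7th percentile) changed sign under spike-in scaling. Osteocyte genes had 2 of 9 higher and 3 lower (51.5th percentile), with Tnfsf11, which encodes the osteoclast factor RANKL, at 2.30 and Ptprz1 at -4.84.

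Part of the adipocyte and chondrocyte genes were higher at day 3. Of 12 adipocyte genes 5 were 2-fold higher and 0 lower, with a median of 0.72 (-0.01 to 2.86) at the 99.98th percentile, and 4 more were higher by a bound. Fabp4 (4.25), Cebpd (3.11), Cebpa (2.86) and Lpl (2.64) led them, and Pparg was at -0.21. Of 6 measured chondrocyte genes 3 were higher (Prg4, 3.59, and Comp, 2.52) and 2 lower (Col10a1, -3.15, and Acan, -1.77). By a bound 5 more were higher, Ucma at least 217-fold. The chondrocyte median of 0.54 over measured members changed sign under spike-in scaling, and was 1.92 with members at their bound. Sox9 was at 1.48. Oxidative stress genes had 4 of 11 higher (Mt2, 4.75; Gpx3, 3.07) and 4 lower (Nqo1, -2.69), at the 67.4th percentile. Inflammatory genes had 4 of 10 higher (Lcn2, 6.88, and C3, 3.88 and 6.42 on its 2 probes) and 3 lower (Ptgs2, -4.16), with 3 more higher and 0 lower by a bound. Their median was 0.27 over measured members (93.8th percentile) and 1.64 with the 3 at their bound.

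The remaining groups had few or no members past 2-fold at day 3. These were the respiratory chain (0 of 14), lysosome and autophagy (0 of 14), cholesterol synthesis (0 of 13) and reference genes (0 of 11, median -0.05, or 0.01 with the 75th percentile of detected spots), and the circadian clock, with 1 of 8 higher (Per1, 1.67) and 2 lower (Nr1d2, -1.97; Nr1d1, -1.85). Blood cell genes were mostly dim: 12 of 18 macrophage genes, Ptprc among them, 7 of 11 granulocyte, 7 of 11 lymphocyte and 7 of 10 erythroid genes were not above background on either array. Of the measured ones, 1 of 6 macrophage genes (Cd14, 1.46; list median 0.63, 99.2nd percentile), 1 of 3 granulocyte genes (Camp, 5.64-fold; 1 lower by a bound), 0 of 4 lymphocyte genes and 0 of 1 erythroid gene were 2-fold higher. Of 7 osteoclast genes 1 was higher (Acp5, 2.64) and 1 lower (Itgb3, -1.39), of 5 endothelial genes 0 passed in either direction (98.6th percentile) with 1 more lower by a bound, and of 2 skeletal muscle genes 1 was lower (Acta1, -2.22). The day 3 array was alone on its slide, so slide and day cannot be told apart here. Of the genes past 2-fold, 49.6% were higher, against 12.3% under spike-in scaling (493 higher, 3517 lower); normexp background correction gave 579 higher and 548 lower.

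**Figure D1:**
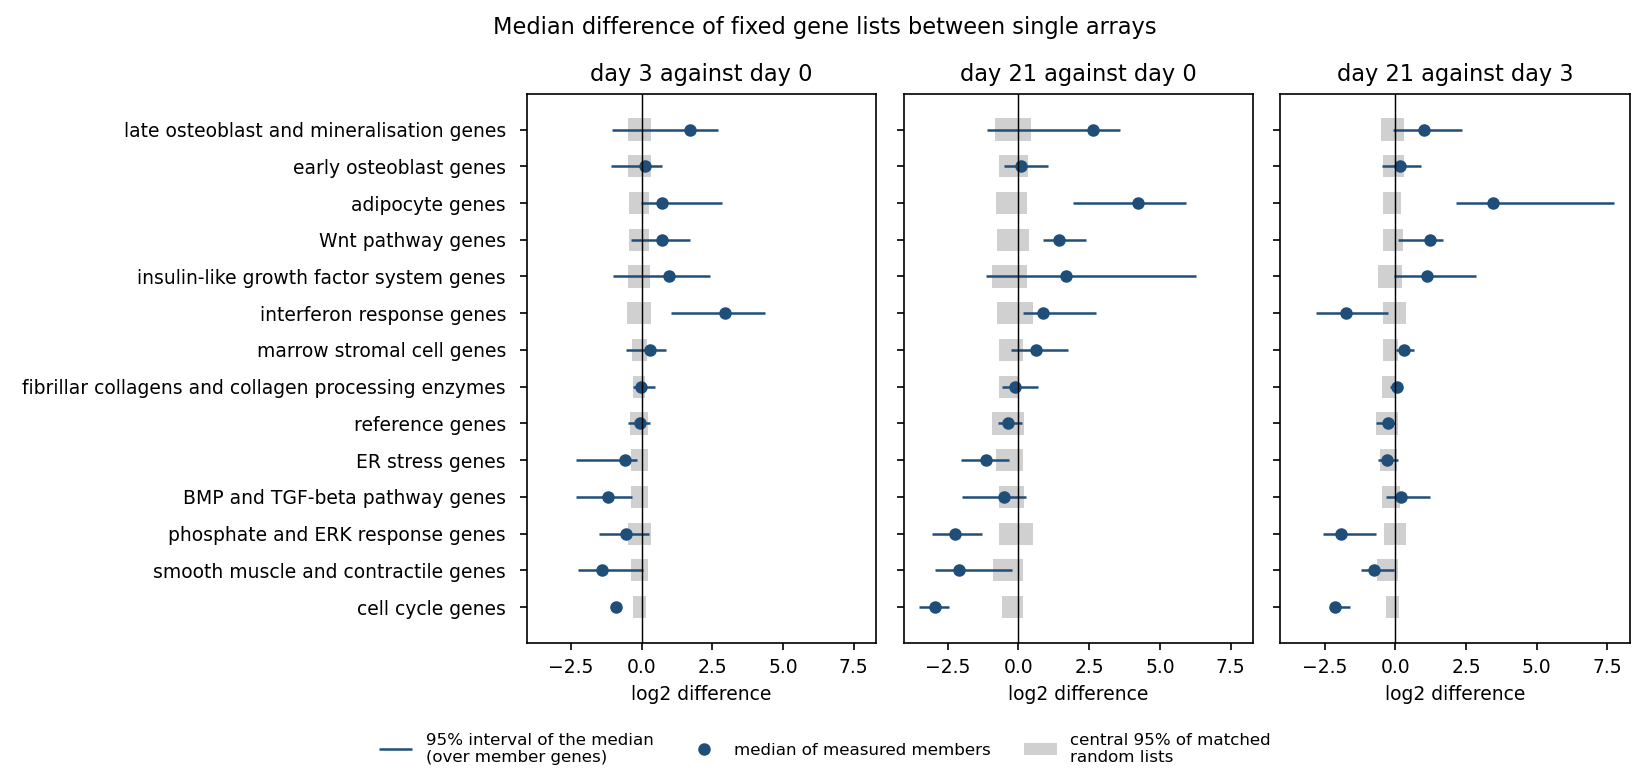
Median log2 difference (horizontal axes) of 14 fixed gene lists in the 3 comparisons, between single arrays. Points are medians over measured members, lines their 95% intervals over genes, and grey bars the central 95% of matched random lists. The adipocyte median reached 4.22 for day 21 against day 0, and the cell cycle median -2.95.

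Day 21 against day 0 asked what differed after the full culture, and both arrays lay on the same slide. All measured adipocyte genes were higher at day 21, most measured late osteoblast genes were higher, and most cell cycle genes were lower. Of 12387 measured genes, 1582 were at least 2-fold higher and 2078 lower, 670 and 520 passed 4-fold, and 168 and 44 passed 16-fold. Another 570 were at least 2-fold higher and 396 lower by a bound. The most raised genes were the adipocyte protease Cfd, also called adipsin (1490-fold), Sult1a1 (723-fold), Lcn2 (517-fold), carbonic anhydrase Car3 (440-fold), C4b (427-fold), Adig (365-fold), the complement inhibitor Serping1 (310-fold) and the fatty acid carrier Fabp4 (301-fold). Among the largest bounds were Hp (at least 14673-fold), Sfrp2 (at least 2161-fold) and resistin, Retn (at least 1931-fold).

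The most lowered genes were the prostaglandin synthase Ptgs2 (147-fold), Slc7a3 (73.9-fold), Nppb (55.9-fold), Mogat2 (51.4-fold), Alkal1 (47.8-fold), Stbd1 (40.8-fold), Fhdc1 (39.4-fold) and the peptide hormone Cck (33.9-fold). By a bound, Olfr781 was at least 135-fold lower, Lce1i at least 122-fold, Ifi27l2b at least 65.8-fold and the neuropeptide Vip at least 64.4-fold.

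Of the osteoblast markers at day 21, Alpl was at least 29.1-fold higher, Ibsp at least 63.7-fold, and the osteocyte matrix gene Dmp1, above background on the day 21 array only, at least 3.20-fold. Spp1 was higher by 2.74, whereas Runx2 (-0.37) and Col1a1 (-0.47) stayed within 2-fold. Of 10 measured late genes 7 were higher and 2 lower, with a median of 2.62 (-1.12 to 3.58) at the 100th percentile. Omd was at 5.26, Bglap2 at 3.58, Bglap3 at 3.56 and Slc20a1 at -3.42. Of 13 early genes 3 were higher (Fgfr2, 1.71; Bmp4, 1.29; Pth1r, 1.04) and Msx2 was lower (-2.93), with a median of 0.07 (-0.51 to 1.04; -0.20 under spike-in scaling) at the 85.3rd percentile. Osteocyte genes had 3 of 9 higher, among them Fbln7 (3.15) and Mepe (5.67-fold), and 2 lower, the lowest at -4.29 (median 0.63, 98.7th percentile). Of the 14 osteocyte genes 5 are also in other lists, Mepe in the late osteoblast list.

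All 12 measured adipocyte genes were at least 2-fold higher at day 21, and 5 more were higher by a bound. Their median was 4.22 (1.92 to 5.91) at the 100th percentile, with Cfd at 10.54, Fabp4 at 8.23, lipoprotein lipase Lpl at 5.91 and the glucose transporter Slc2a4 at 5.05. Pparg, the adipocyte transcription factor, was at 1.92. The hormone Adipoq was at least 1238-fold and the lipid droplet gene Cidec at least 1718-fold higher. Of 6 measured chondrocyte genes 3 were higher (Comp, 6.67; Prg4, 6.16; Sox9, 1.24) and Col10a1 was lower (-1.27), at the 93.2nd percentile. By a bound 1 more was lower and 6 were higher, Ucma at least 339-fold and Cnmd at least 297-fold. The chondrocyte median was 0.46 over measured members, which the percentile covers, and 3.41 with members at their bound. Of 6 macrophage genes 3 were higher (Cd14, 2.22; Lyz2, 1.55; Lyz1, 1.18). Ptprc was not above background, and the list's median over measured members was 0.85 (98.5th percentile). When dim genes were kept at the lowest detected value of each array, the median was -0.45. That value is the difference between these lowest values, since 11 of 18 genes were dim on both arrays, and does not describe macrophage genes. The near-identical Lyz1 and Lyz2 are uncertain singly.

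Cell cycle genes were lower in 25 of 27 measured cases with 0 higher, and the median was -2.95 (-3.50 to -2.45) at the 0th percentile. Birc5 (-3.81), Plk1 (-3.75), Mki67 (-3.74) and Ccna2 (-3.70) led them. Cell cycle inhibitors had 5 of 11 higher (Sesn1, 3.88; Cdkn1c, 3.03; Cdkn2c, 2.55; Cdkn2a, 1.82) and 1 lower (median 0.41, 99.3rd percentile). ERK response genes had 10 of 12 lower and 0 higher (median -2.24, -3.04 to -1.30, 0th percentile), led by Etv4 (-4.22) and Dusp4 (-3.62). Contractile genes had 9 of 13 lower and 0 higher (median -2.09, 0th percentile), led by Actg2 (-4.34) and Cnn1 (-3.86). ER stress genes had 8 of 15 lower and 0 higher (median -1.15, 0.02nd percentile), led by Chac1 (-4.41). Hypoxia and glycolysis genes had 7 of 16 lower and 3 higher (median -0.85, 1.26th percentile), with Ndrg1 at 3.13 and Egln3 at -2.05. Cholesterol synthesis genes had 3 of 13 lower, among them Sqle (-1.01), at the 3.17th percentile, and the respiratory chain 1 of 14 (Cycs, -1.37) at the 70.2nd.

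At day 21 Wnt pathway genes had 8 of 13 measured higher and 0 lower, with 2 more higher and 3 lower by a bound (median 1.44, 0.85 to 2.38, 100th percentile), led by the inhibitors Sfrp1 (6.39), Wif1 (3.38) and Sfrp4 (2.38). The insulin-like growth factor system had 4 of 8 higher and 1 lower, with 1 more each way by a bound (median 1.69, 100th percentile), with Igfbp3 at 6.28 and Igfbp5 at 4.02. BMP and TGF-beta pathway genes had 3 of 18 higher (Bmp6, 2.47) and 8 lower, among them Inhba (-3.51), at percentile 11.02. Interferon response genes had 4 of 11 higher and 0 lower (median 0.87, 99.6th percentile), with Oasl2 at 2.88 and Oas1a at 2.75. Inflammatory genes had 4 of 10 higher (Lcn2, 9.01; C3, 7.82 and 10.37 on its 2 probes) and 5 lower (Ptgs2, -7.20; Il6, -3.61); the median was -1.13 over measured members (0.18th percentile) and 1.14 with 3 higher members at their bound.

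Marrow stromal genes had 8 of 20 higher (Angpt1, 5.45; Pdgfra, 5.12) and 5 lower (Nes, -4.44), with a median of 0.62 (99.97th percentile). Non-collagenous matrix genes had 6 of 20 higher (Lum, 5.50; Ogn, 4.69; Dcn, 2.26) and 6 lower (Tnc, -3.21); their median of 0.21 (99.8th percentile) changed sign under spike-in scaling. Collagen genes had 6 of 26 higher (Col14a1, 6.82 and 3.72 on its 2 probes; Adamts2, 3.87) and 3 lower (Loxl2, -2.98), at the 89.4th percentile. Proteases and inhibitors had 4 of 13 higher and 0 lower (median 0.34, 98.9th percentile), led by Mmp19 (3.05). By a bound 3 more were higher and 0 lower, and the median was 0.82 with these at their bound. Lysosome genes had 0 of 14 past 2-fold, and their median of 0.24 (99.4th percentile) changed sign under spike-in scaling. Oxidative stress genes had 4 of 11 higher (Gpx3, 4.49) and 3 lower (Nqo1, -2.68); their median of 0.26 changed sign under spike-in scaling, and was -0.11 with the member at its bound.

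Notch pathway genes had 2 of 7 higher (Notch3, 2.08; Heyl, 1.41) and 1 lower (Hes1, -1.85), and clock genes 3 of 8 higher (Per1, 1.81), with 2 more higher and 1 lower by a bound. Reference genes had 1 of 11 lower (Gapdh, -1.16) and a median of -0.38 (55.6th percentile). Osteoclast genes had 1 of 7 higher (Acp5, 3.57) and 1 lower, granulocyte genes 1 of 3 higher (Camp, 2.63; 2 higher and 1 lower by a bound), endothelial genes 1 of 4 higher (Flt1, 2.78; 1 higher and 2 lower by a bound), skeletal muscle genes 1 of 2 higher (Tnnc2, 1.42) and 1 lower (Acta1, -3.92), and lymphocyte (0 of 4) and erythroid genes (0 of 2) none. Of the genes past 2-fold, 43.2% were higher, against 54.4% with the 75th percentile of detected spots (1874 higher, 1572 lower) and 27.8% under spike-in scaling (1236 higher, 3217 lower).

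**Figure D2:**
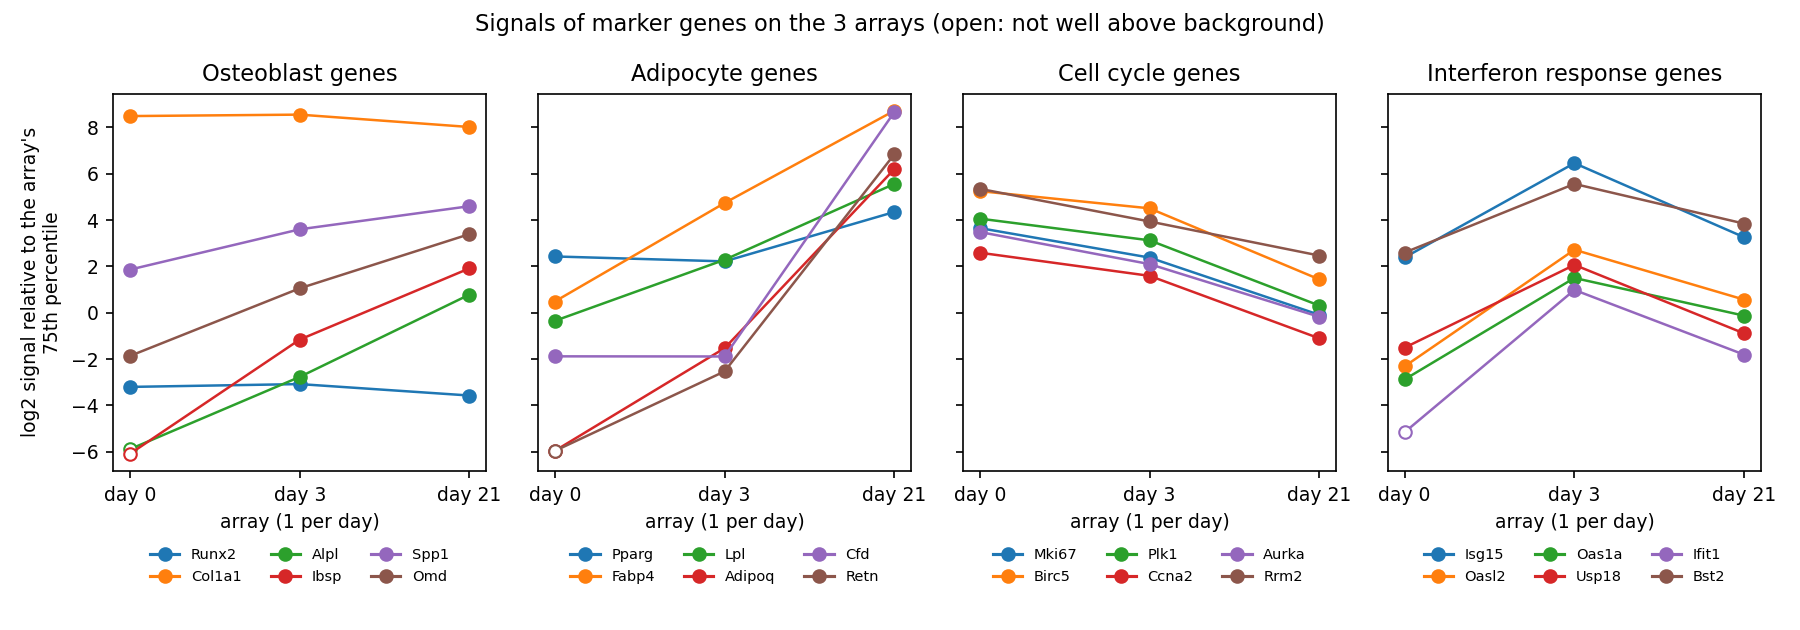
Log2 signal relative to the array's 75th percentile (vertical axis) for 24 genes on the day 0, day 3 and day 21 arrays, 1 point per array, open where not well above background. Lines are to be followed within a gene, since levels of different probes are not comparable. Cfd was at 10.54 above its day 0 value at day 21, and Isg15 at 4.07 above it at day 3 and 0.87 at day 21.

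Day 21 against day 3 asked which differences came after the first days. Most adipocyte genes were higher than at day 3, and most cell cycle and interferon response genes were lower. Of 12739 measured genes, 987 were at least 2-fold higher and 906 lower, and 31 and 1 passed 16-fold. Another 251 were at least 2-fold higher and 225 lower by a bound. The most raised genes were Cfd (1496-fold), the lipogenic regulator Thrsp (1251-fold), Car3 (821-fold), Retn (660-fold), Cidec (565-fold), Adig (329-fold), Adipoq (212-fold) and Apoc1 (134-fold). By a bound Cyp2e1 was at least 144-fold, Cox8b at least 109-fold and Slc36a2 at least 83.8-fold higher. The most lowered were Mogat2 (17.3-fold), the retinoic acid binding protein Crabp1 (11.8-fold), Aunip (11.2-fold), the kinetochore gene Ska1 (-3.34), the linker histone H1f5 (9.80-fold), Isg15 (9.17-fold), the mitotic kinase Melk (8.82-fold) and Hmga2 (8.79-fold). Mcpt8 was at least 16.7-fold, E2f8 at least 11.3-fold, Bub1 at least 11.04-fold and Pkp1 at least 10.4-fold lower.

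Of 16 measured adipocyte genes 14 were higher and 0 lower between day 3 and day 21 (median 3.47, 2.15 to 7.73, 100th percentile), and Pparg was at 2.13. Late osteoblast genes had 5 of 11 higher and 0 lower (median 0.998, -0.08 to 2.34, 100th percentile), with Ibsp at 3.07, Omd at 2.34, Mepe at 2.10 and Spp1 at 0.998, just under 2-fold. Dmp1 was at least 3.14-fold higher. Early osteoblast genes had 2 of 12 higher (Alpl, 3.55; Bmp4, 1.36) and 1 lower (Msx2, -1.12), at the 92.8th percentile, with Runx2 at -0.49 and Col1a1 at -0.53. Osteocyte genes had 2 of 9 higher and 1 lower (median 0.55, 99.3rd percentile). Chondrocyte genes had 7 of 13 higher and 0 lower (median 1.35, 0.21 to 3.16, 100th percentile), led by Snorc (5.16), Comp (4.14) and Cnmd (3.16), with Sox9 at -0.25. Cell cycle genes had 23 of 27 lower and 0 higher (median -2.13, -2.27 to -1.61, 0th percentile), with Birc5 at -3.07 and Mki67 at -2.47. ERK response genes had 7 of 12 lower and 0 higher (median -1.91, 0th percentile), led by Egr1 (-3.02) and Fos (-2.71). Interferon response genes had 10 of 14 lower and 0 higher (median -1.75, -2.79 to -0.26, 0th percentile), led by Isg15 (-3.20), Usp18 (-2.96) and Ifit1 (-2.79). Contractile genes had 5 of 13 lower (0.54th percentile).

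Wnt pathway genes had 9 of 15 higher (median 1.22, 100th percentile) and insulin-like growth factor genes 5 of 9 (median 1.12, 100th percentile, or 0.75 with 1 lower member at its bound), with 0 measured members lower in both, led by Sfrp2 (3.22) and Igfbp5 (3.06). Clock genes had 5 of 10 higher and 0 lower (median 1.02, 0.14 to 1.58, 100th percentile), led by Nr1d1 (2.10). BMP and TGF-beta genes had 5 of 19 higher (Chrdl1, 4.90; Bmp7, 2.69) and Notch genes 2 of 7 (Heyl, 2.25; Hey1, 1.96) with 1 lower. Cholesterol synthesis genes had 2 of 13 lower (median -0.73, 0.01st percentile). Inflammatory genes had 4 of 13 higher and 5 lower. Proteases had 5 of 16 higher, stromal genes 3 of 20 with 2 lower, matrix genes 3 of 20 with 2 lower, collagens 2 of 26 with 1 lower, and lysosome genes 0 of 14. The day 3 array again lay on the other slide, so slide and day cannot be told apart. Of the genes past 2-fold, 52.1% were higher, against 62.6% with the 75th percentile of detected spots (1157 higher, 691 lower), 64.5% without scaling (1191 higher, 656 lower) and 78.5% under spike-in scaling (1614 higher, 443 lower), whereas median scaling gave 46.3% (897 higher, 1041 lower) and genes above background on all 3 arrays 46.7% (775 higher, 883 lower); normexp gave 611 higher and 466 lower.

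The early and late differences from day 0 overlapped. Among 12221 genes measured on all 3 arrays, 957 were higher at day 3 and 1571 at day 21, and 827 in both, where independent lists would share 123.0. Of 907 lower at day 3 and 2062 at day 21, 722 were shared, against 153.0, and 12 genes went opposite ways. The day 0 array cannot be split, so part of the excess may come from it. Between day 3 and day 21, 280 of the higher genes were at least 2-fold higher again, among them Fabp4 and C3, and 74 were at least 2-fold lower, among them Isg15, Usp18 and Oasl2. Of the lower genes 195 were 2-fold lower again, among them Ptgs2 and Stbd1, and 64 were 2-fold higher again, among them Nr1d1 and Col10a1.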

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

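No test was run on the results in this part, and no biological explanation was tested. Probes without a gene name lie outside the comparisons of genes, and many of them differed between days. At least 2-fold higher were 364 of 7650 measured for day 3 against day 0, 547 of 7744 for day 21 against day 0 and 394 of 7770 for day 21 against day 3. The lower ones were more frequent, with 492, 1565 and 1259 in the same order. The lower ones made up 20.2% of the measured unnamed probes for day 21 against day 0, where genes gave 16.8%, 16.2% for day 21 against day 3, where genes gave 7.11%, but 6.43% for day 3 against day 0, where genes gave 7.85%. Of 2772 spots of ERCC control probes, meant for an added RNA mix that the labels do not mention, 71 were well above background at day 0, 125 at day 3 and 81 at day 21. Many were repeat spots of few probes. Of 96 ERCC probes only 2, 3 and 2 were well above background in the same order, and ERCC-00148_99 gave 28 of these spots on each array.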

How the results depend on the processing

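The alternatives were listed before the data were examined, except those for the 8 added gene lists, and the count of scalings below was chosen after its result was seen. Of the list medians under the alternatives, 1142 stayed within the main interval or range, 29 left it and 9 outside the range of random lists changed sign, while 48 within that range, counted above by size only, also changed sign. Of the values of named genes, 4348 stayed within the technical SD, 932 moved further and 0 of those past 2-fold in the main setting changed sign. Of the counts, 67 stayed within 1.5 times the main count and 29 did not. The deposited value table gave the same counts. Spike-in scaling moved the median of all measured genes by -0.59 for day 3 against day 0, -0.28 for day 21 against day 0 and 0.32 for day 21 against day 3. For day 21 against day 0 the 75th percentile of detected spots moved it by 0.17, no scaling by 0.15 and quantile normalization by 0.11, and for day 21 against day 3 the first 2 moved it by 0.11 and 0.13. Differences hold relative to these shifts. One factor per array leaves a list's percentile as it is, by construction.

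For day 3 against day 0, 579 genes were higher and 548 lower after normexp, 493 and 3517 under spike-in scaling, 497 and 314 at 3-fold, and 1854 and 2395 at 1.5-fold. For day 21 against day 0, 3217 were lower under spike-in scaling, 951 higher and 839 lower at 3-fold, and 2462 and 3938 at 1.5-fold. For day 21 against day 3, 611 were higher and 466 lower after normexp, 1614 and 443 under spike-in scaling, 435 and 273 at 3-fold, and 1940 and 2494 at 1.5-fold. Genes shared by day 3 and day 21 numbered 509 higher and 454 lower after normexp, 453 and 2184 under spike-in scaling, 438 and 226 at 3-fold, and 1450 and 1844 at 1.5-fold. The cell cycle median was -1.50 for day 3 against day 0 under spike-in scaling and -1.60 for day 21 against day 3 after normexp. The normexp offset of 50 compresses folds of dim genes and each spike-in or size setting shifts counts by construction.

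Of the medians outside the range of random lists, the sign changed under spike-in scaling for non-collagenous matrix (-0.063), lysosome (-0.037) and oxidative stress genes (-0.013) for day 21 against day 0, and for marrow stromal (-0.30), chondrocyte (-0.058) and cell cycle inhibitor genes (-0.17) for day 3 against day 0. With dim genes kept at the floor it changed for macrophage (-0.45) and oxidative stress genes (-0.11) for day 21 against day 0. The macrophage value is the difference between the floors of the 2 arrays, since 11 of 18 genes were dim on both. Median scaling changed the sign for lysosome genes (-0.0083) for day 21 against day 3. The cause of the oxidative stress and lysosome changes was not tested. Among the 48 others were the early osteoblast medians, -0.47 for day 3 and -0.20 for day 21 against day 0 under spike-in scaling. More genes were lower than higher at day 21 against day 0, but 2 of 6 other scaling and background settings gave more genes higher, so the balance of directions may come from the scaling. No paired analysis was possible because there was 1 array per group and the labels give no replicate numbers. Leaving out a replicate and a slide block were not run for the same reason.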

Other observations

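The tests of slides, scaling, blood cells and handling in this part were chosen after the results were seen; the others were fixed before their own result, on gene lists written after the largest differences had been seen, except that the condition for setting interferon transcripts aside was loosened after its result was seen. Several groups not yet described differed. Serine synthesis and amino acid response genes were lower at day 3 against day 0 in 11 of 19 measured cases, with 0 higher and a median of -1.27 (-2.02 to -0.80), led by Cth (-3.02), Mthfd2 (-2.60), the arginine and lysine transporter Slc7a1 (-2.36) and Psph (-2.32). At day 21 against day 0 the count was again 11 of 19, with a median of -1.72. YAP target genes were lower in 7 of 15 cases at day 3 (median -0.82), led by Ankrd1 (-2.77) and Crim1 (-2.11), and in 10 of 15 at day 21 (median -1.16). Complement genes beyond those already named were higher at day 21 against day 0 in 4 of 6 measured cases, with 3 more by a bound and a median of 3.77 (0.10 to 5.29), led by C1s1 (5.29) and C1ra (4.13). MHC class I presentation genes were higher in 7 of 9 cases at day 3 and 8 of 9 at day 21 (median 1.89), led at day 21 by the immunoproteasome subunits Psmb9 (4.03) and Psmb8 (2.81).

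The low level of Slc7a3 and Trib3 at day 3 may belong to a lower amino acid response, tested as a lower amino acid response at day 3 than at day 0: the median of the wider list lay at percentile 0 of matched random lists. Trib3 also led the falls among ER stress genes (median -0.58, 0.07th percentile). The wider list could not tell an amino acid response from lower ER stress. Lower YAP activity is a candidate explanation for the contractile genes, and YAP targets lay at percentile 0.01. Higher expression across further complement genes may include C3, C4b, Serping1 and Cfd, since the further complement genes lay at percentile 100. These lists follow RNA of single arrays, and none of them measures a pathway's activity.

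Genes known to respond to glucocorticoids were high at day 3, although the labels name no glucocorticoid among the additives. Of 13 measured, 9 were at least 2-fold higher than at day 0 and 0 lower, with a median of 1.86 (0.72 to 2.86), and at day 21 12 were higher and 1 lower (median 2.89). Glul (3.78), Fkbp5 (3.28), Tsc22d3 (2.86) and Errfi1 (2.81) led at day 3, and by a bound, chosen after its value was seen, Zbtb16 was at least 119-fold higher. The list's median was at percentile 100 of matched random lists, which describes these genes and is no separate test of a glucocorticoid response. Other inducers of these genes were not tested, and a glucocorticoid in the medium was not measured.

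The adipocyte genes at day 21 stand out in a culture induced for bone. A difference between slides would leave them level within a slide, yet their median was 4.22 between day 21 and day 0, which share one. The lowest median over the scaling and background settings was 3.94, under spike-in scaling. That setting shifts all genes by -0.28 in this comparison, so 3.94 follows by construction. A shift of that size is small beside 4.22. Macrophages are argued against by few macrophage genes being at least 2-fold higher, 3 of 18, with 11 dim on both arrays. Ptprc, Tyrobp and Laptm5 were not above background. Of 6 measured members, however, 3 were higher (median 0.85, 98.5th percentile). In this list 6 genes were above background at day 0 and 7 at day 21, and 0 are in another list. Other blood cells were tested through Ptprc alone. Of 3 measured granulocyte genes 1 was higher, with 2 more higher and 1 lower by a bound. Of the measured lymphocyte (0 of 4) and erythroid genes (0 of 2) none was higher. Triglyceride synthesis and lipolysis genes were higher in 10 of 15 measured cases, with Acsl1 at 4.35 and the lipase Pnpla2 at 3.61 (median 2.02, percentile 100). That result goes with adipocytes in the culture, a hypothesis found and tested on the same arrays. RNA of a whole culture cannot show whether osteoblasts lay beside them, and a mixed or mislabelled culture stays open. Whether such adipocytes would be of the brown kind cannot be told apart. Of 12 brown adipocyte genes 4 were at least 2-fold higher (Dio2, 5.83, and Lhx8, 1.93, as measured, and Cidea and Cox8b by a bound), but Ucp1 was not above background on any array.

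The interferon response genes were highest at day 3. A uniform shift of the day 3 array would not place the list at percentile 100 against day 0 and at percentile 0 for day 21 against day 3. These percentiles are the pattern itself and both rest on the same day 3 array, so a slide effect on these genes alone stays open. Macrophages are argued against by 1 of 18 macrophage genes being 2-fold higher, with 12, among them Ptprc, Tyrobp and Laptm5, not above background. The 6 measured ones had, however, a median of 0.63 (99.2nd percentile). Other blood cells were tested through Ptprc alone. MHC class I presentation genes were high too (median 1.57, percentile 100), which is consistent with a wider interferon response, but they were not lower for day 21 against day 3 (median 0.57, 2 of 10 higher, 0 lower), so a single shared response stays open. Interferon transcripts remain open: 0 of 8 ligand genes were 2-fold higher, but 6 were not above background on either array. The condition used, that no ligand gene be 2-fold higher, was the one loosened after its result was seen. That condition was wrong for genes this dim and could not exclude a low or earlier transcript. Separate handling of the day 3 culture cannot be told apart from the day, because 0 further day 3 arrays exist here, although within the other slide 4 of 11 interferon genes were also higher at day 21 than at day 0.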
